A study of Mus musculus with 6 samples.

How the data were processed

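The study profiled messenger RNA of mouse bone marrow B cells by paired-end sequencing on an Illumina NextSeq instrument, per the labels and the design text of the series. Per the labels, the cells came from pre-tumoral mice 6 to 8 weeks old that carry the Eµ-myc transgene, loxP-flanked alleles of Prmt5 and a tamoxifen-inducible Cre recombinase, and they were cultured with interleukin 7 at 5 ng/µl. Per the labels' protocols, Prmt5 was deleted with 50 nM 4-hydroxytamoxifen (4-OHT) for 24 h, controls received ethanol, and the cells were then washed and cultured for 5 days more. RNA was extracted with Trizol and a column kit and made into libraries with the TruSeq RNA kit, per the labels' protocols.

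The labels hold a conflict. The 6 libraries are titled WT (3 libraries) and PT (3 libraries), and the design text of the series speaks of wild-type and pre-tumoral mice. The sample characteristics give one genotype for all 6 libraries, ethanol for those titled WT and 4-OHT for those titled PT. The header and rows of the deposited table name its conditions for ethanol and 4-OHT. Both readings divide the libraries in the same way, and the conditions are called ethanol and 4-OHT here, as in the table and the characteristics. No value was used to place a library in a group.

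The deposited table holds 21307 rows, each with a gene name, a locus, 1 FPKM value (mapped fragments scaled to the length of the transcript and the size of the library) for ethanol and 1 for 4-OHT, and a log2 fold change. The FPKM values were computed by the authors, and each stands for a whole condition. How the 3 libraries were combined and whether the conditions were scaled to each other is not given in the sources used here. Per the submitters' processing notes the tools were CASAVA, TopHat2 2.0.9 and Cufflinks 2.1.1, with genome build mm9. The log2 fold changes deposited by the authors are the log2 of the 4-OHT value over the ethanol value, with no pseudocount: all 15756 rows above 0 in both conditions matched that ratio within 0.01. No column of values was left unmatched to a condition.

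Because the table has 1 value per gene and condition, the planned linear models, gene set tests and other tests across libraries were not run. No difference has a replicate check, no p-value, SD or n is given, and read depth is unknown, so no counting interval is given either. Differences are described by their size alone. The ratio is log2 of (FPKM + 1) in 4-OHT over (FPKM + 1) in ethanol. It understates the change of genes with low values, and every fold printed is on this scale unless the authors' deposited table is named. Rows entered when the mean of both conditions was at least 1 FPKM and both values were above 0, which left 10856 rows. Of these, 81 merge several gene names and 21 are small RNAs, for which FPKM is unstable because the transcripts are about as short as the sequenced fragments.

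A value of exactly 0 can be a failed estimate. In 5 rows a high ethanol value stands beside a 4-OHT value of 0 and a listed fold change of 0. The 282 other rows at 0 in 4-OHT alone list an infinite fold change. Eef1a1, a translation elongation factor that every cell uses, is listed at 0 in both conditions. Zeros are therefore reported only as listed.

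Gene lists (38, for B-cell stages, MYC and splicing functions, growth, stress, other cell types of the bone marrow and library checks) and the rule for named genes were fixed before the data were examined. For each list with at least 5 compared members, 34 in all, the median ratio was set among the medians of 10000 random lists of the same size, drawn from the compared rows and matched over 20 bins of mean FPKM. The percentile describes these pooled values and is not a p-value. A list was called apart when its median lay outside the central 95% of the random medians. About 1.7 of 34 lists would do so by chance if their members varied independently, which genes of a shared function need not do. The ribosomal protein and mitochondrial genome lists were not analysed here because none of their names was matched in the table used. The named genes were Myc, Prmt5, Wdr77, Clns1a and Smn1, the 12 highest and 12 lowest ratios among the 8129 rows with a mean of at least 5 FPKM, and the 2 members with the highest mean FPKM in each list. The rule also required an adjusted p-value and no overlap between libraries, and these conditions could not be applied. Other genes named in the text were chosen after their values were seen.

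Coordinates are the loci of the table, on mm9. Locus lengths were compared with the lengths of the RefSeq genes of GRCm38, matched by name for 18851 rows. They were equal in 6341 rows when the start is counted from 0 and in 437 when it is counted from 1, so 1 was added to each start. A locus can span several genes. The reference used here is GRCm38, so it served only for names and this check of lengths.

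Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The ratio and the list percentile were tested on simulated data for the 10856 rows of the comparison of 4-OHT with ethanol, with 200 rows changed 4-fold. Of the 156 changed rows with a mean of at least 5 FPKM, 95.5% passed 2-fold in the right direction. Of 20 unchanged lists 1 was called apart, as were 10 of 10 changed lists. The simulated genes varied independently, and most members of each changed list were raised 4-fold. The simulation therefore does not cover lists whose genes vary together, or smaller shifts. The alternatives tried were pseudocounts of 0.1 and 0.5, no filter and a minimum of 5 FPKM, median-of-ratios scaling, and quantile normalization. Chosen after the data were seen were the authors' deposited fold change, the removal of small RNAs and merged rows, and the removal of the members of the lists of other cell types.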

Results

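RNA sequencing compared cultured bone marrow B cells of Eµ-myc mice treated with ethanol with cells treated with 4-OHT, which activates Cre and deletes Prmt5, the arginine methyltransferase that methylates spliceosomal Sm proteins. Eµ-myc mice express MYC, a growth-promoting transcription factor, under an immunoglobulin enhancer and develop B-cell lymphoma. Each condition had 3 libraries, and the deposited values are 1 FPKM per gene and condition. The listed FPKM summed to 346977 in ethanol and to 356802 in 4-OHT, and the Spearman correlation of the conditions across all rows was 0.973 (genes are not independent replicates). No value has a replicate error, so every difference below is one of size, without a test.

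The question of the series is how MYC and PRMT5 act on the splicing machinery. The values, 1 FPKM per gene and condition, measure neither the splicing of transcripts nor the methylation of Sm proteins. Prmt5 (chromosome 14, 55126019 to 55136307) stood at 41.6 FPKM in ethanol and at 5.71 FPKM in 4-OHT. This is 6.35-fold lower (log2 ratio -2.67), the second lowest ratio of the 8129 genes with a mean of at least 5 FPKM. Vpreb2, with nearly the same ratio, was lower than Prmt5 under quantile normalization. The authors' deposited table lists a log2 fold change of -2.86 for Prmt5. Myc (chromosome 15, 61816896 to 61821916) stood at 402 FPKM in ethanol and 213 FPKM in 4-OHT, 1.88-fold lower (log2 ratio -0.91). The ethanol condition, whose libraries are titled WT, held the higher Myc value.

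In all, 1124 genes were at least 2-fold higher and 280 were at least 2-fold lower in 4-OHT, or 10.4% and 2.58% of the 10856 compared. With a pseudocount of 0.1 the counts were 1499 and 457, and with a minimum of 5 FPKM they were 700 and 218. The median log2 ratio of all compared genes was -0.07. The 12 highest ratios ran from 11.5-fold to 19.7-fold. They were led by genes of the extracellular matrix: the fibrillar collagens Col3a1 (4.55 FPKM in ethanol, 108 FPKM in 4-OHT), Col1a1 and Col1a2, the beaded-filament collagens Col6a1 and Col6a2, and Bgn, Sparc and Mgp. The others were Igfbp3, which encodes a binding protein for insulin-like growth factors, the granulocyte precursor genes Mpo (16.4 and 222 FPKM) and Ms4a3, and Rmrp, a short noncoding RNA whose FPKM is unstable. Rmrp lay above Col3a1 with a pseudocount of 0.1 (log2 ratios of 4.85 and 4.54) or 0.5, and with the authors' deposited fold changes. The 12 lowest ratios ran from 4.30-fold to 9.57-fold lower. They held Myl10, a myosin light chain gene, at 373 FPKM in ethanol and 38.1 FPKM in 4-OHT, Prmt5, and Vpreb2, a surrogate light chain gene of pre-B cells, at 272 and 42.0 FPKM. Gldc, which encodes the glycine-cleaving decarboxylase of mitochondria, stood at 52.2 and 8.71 FPKM. Cth, which encodes cystathionine gamma-lyase of cysteine synthesis, stood at 75.5 and 15.2 FPKM. The remaining ones were Bhlha15, a transcription factor gene of secretory cells, the imprinted noncoding RNA H19, the chaperone gene Clgn, Gm266, Epb4.1l4b, Ttll11 and Ng23.

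**Figure D1:**
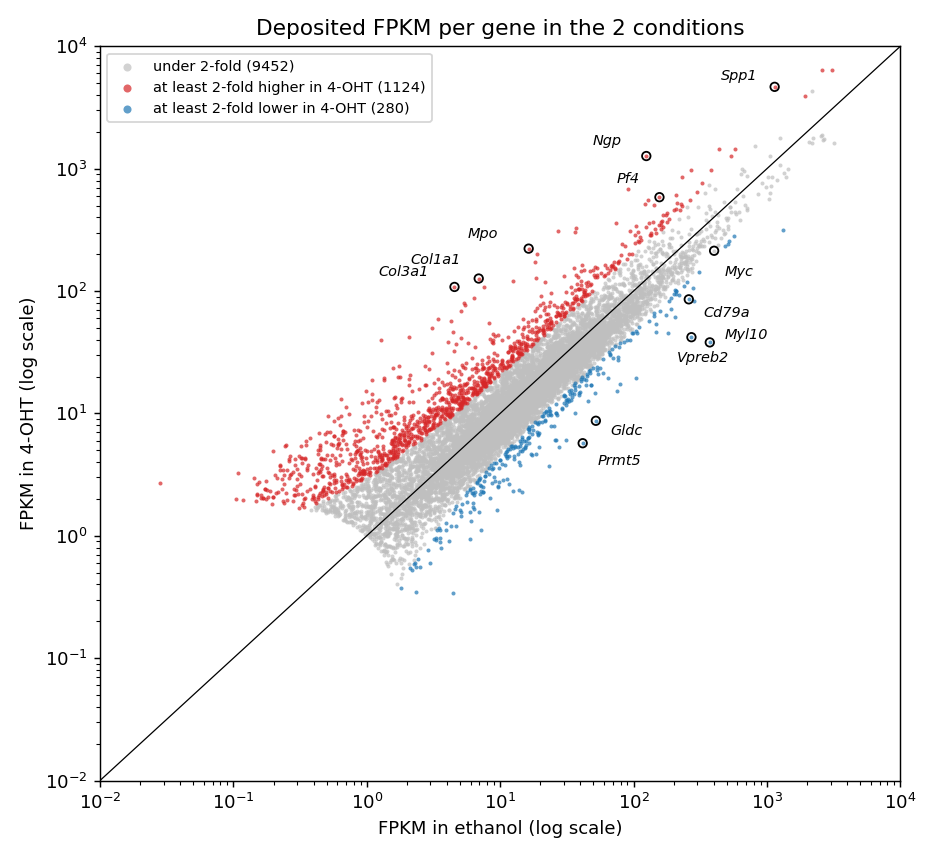
Deposited FPKM of each of the 10856 compared genes in ethanol (horizontal axis, log scale) and in 4-OHT (vertical axis, log scale), 1 value per gene and condition. Red points are the 1124 genes at least 2-fold higher and blue points the 280 genes at least 2-fold lower in 4-OHT on the log2(FPKM + 1) scale, the line marks equality, and Prmt5 lies far below it at 41.6 and 5.71 FPKM.

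Genes of early B cells were lower in 4-OHT. Of 35 compared members of the pro-B and pre-B cell list, 32 were lower and 10 of these at least 2-fold. The list median was -0.73, below all 10000 random lists (percentile 0). The surrogate light chain genes Vpreb1 (180.5 and 45.7 FPKM in ethanol and 4-OHT) and Igll1 (206 and 61.0 FPKM), and the antigen receptor subunit gene Cd79a (260 and 85.6 FPKM), had log2 ratios of -1.96, -1.74 and -1.59. Vpreb3 (509 and 242 FPKM) and the surface gene Cd24a (451 and 273 FPKM) had log2 ratios of -1.07 and -0.72. Pax5 and Ebf1, transcription factor genes of B-cell identity, had log2 ratios of -0.89 and -1.10, whereas the recombinase gene Rag1 was near equal, at -0.03. Kit, a receptor gene of progenitors that mast cells also use, was higher, at 0.866 and 5.01 FPKM. Vpreb1 and Vpreb2 are near-identical copies, so reads may have been split between them.

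Later B-cell stages did not shift as a group. In the immature and mature B cell list, 15 of 30 members were higher and 15 lower, with a median of 0.01 (percentile 73.6). Within it the chemokine receptor gene Cxcr5 was at 12.4 and 2.33 FPKM. The most abundant members, the tetraspanin gene Cd37 and a merged row that holds Il4i1, had log2 ratios of -0.54 and -0.43. The plasma cell list had a median of -0.01 (percentile 65.7). It held 2010001M09Rik, also named Mzb1 (285 and 82.4 FPKM), at -1.78 and Xbp1, a transcription factor gene of secretory cells, at -0.01. Its members went apart: 7 of 11 were lower, with Mzb1 and Igj (-1.71) at least 2-fold lower. The other 4 were higher, up to 0.94 for Sdc1. In the class II antigen presentation list, 7 of 12 members were higher, with a median of 0.42 (percentile 95.3), and the list stood apart, at 0.57, with a minimum of 5 FPKM. Its most abundant members went apart: the lysosomal protease gene Ctss was at 817 and 1540.3 FPKM and Cd74, the invariant chain gene, in a row merged with a microRNA, at 497 and 399 FPKM. In the list of the response to interleukin 7, the median was -0.07 (percentile 58.4), with 8 of 19 members higher and 11 lower. The feedback inhibitor genes went apart: Socs2, Socs1 and Cish were at -1.68, -1.22 and -1.12, and Socs3 was at 1.04. The most abundant members, Ccnd3 and Pim1, were at -0.31 and -0.52.

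Genes of other bone marrow cells were higher in 4-OHT, and many were abundant in both conditions. Of the 9 lists of other cell types, 7 had a median above the random lists. In the neutrophil and granulocyte precursor list, 20 of 21 members were at least 2-fold higher, with a median of 2.55 (percentile 100). Its most abundant genes, the granule genes Ngp (125 and 1269 FPKM) and Lcn2 (90.7 and 687 FPKM), had log2 ratios of 3.34 and 2.91. In the stromal and endothelial list, 20 of 21 were at least 2-fold higher, with a median of 2.08 (1.93 to 3.57 under the alternatives). Its most abundant members were Col1a1 (6.91 and 127 FPKM) and Sparc (7.56 and 108 FPKM). The megakaryocyte and platelet list had a median of 1.69, with 15 of 16 members at least 2-fold higher and the chemokine genes Pf4 at 156 and 585 FPKM and Ppbp at 42.8 and 149.8 FPKM. The mast cell, basophil and eosinophil list had a median of 1.33, with 12 of 14 at least 2-fold higher, among them Prss34 and Prg2 at log2 ratios of 1.62 and 1.94. In the monocyte and macrophage list, 21 of 22 members were higher, 14 of them at least 2-fold, with a median of 1.10. Its most abundant compared members were the heme oxygenase gene Hmox1 (167 and 419.5 FPKM) and the complement gene C1qb (162 and 365.5 FPKM). The list member Lyz2 was not compared because it is listed at 0 in 4-OHT. Its ethanol value, 3835 FPKM, was the highest of all rows in ethanol. Of genes chosen after their values were seen, Apoe, a lipoprotein gene that macrophages express strongly, was at 2174 FPKM in ethanol and 4314 FPKM in 4-OHT, and Spp1, the osteopontin gene, was at 1143 and 4667 FPKM.

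The lists of lymphoid, dendritic and erythroid cells held few expressed genes. The erythroid list had a median of 1.09 over 7 members (percentile 99.6), with the transcription factor gene Nfe2 at 8.88 and 39.8 FPKM and the carbonic anhydrase gene Car2 at 9.70 and 5.31 FPKM. With no filter on low values the erythroid median was 0.04 and the list did not stand apart. The median was 1.88 with a pseudocount of 0.1 and 1.96 with the authors' deposited fold changes. The natural killer cell list had a median of 0.92 over 5 members (percentile 97.9), with Ccl5 and Nkg7 at log2 ratios of 0.92 and 2.48, and this list no longer stood apart with a pseudocount of 0.1 or 0.5, with no filter (median 0.28) or with the authors' deposited fold changes. The T cell list (median 0.38 over 12 members, percentile 90.2; 0.04 with a minimum of 5 FPKM and 0.19 under quantile normalization) and the dendritic cell list (0.70 over 9, percentile 96.9) lay within the random lists. The dendritic cell list stood apart with pseudocounts of 0.1 and 0.5 and with the authors' deposited fold changes (medians 1.10, 0.91 and 1.15), and its median was 0.19 with no filter. Their most abundant members were Cd2 and Lat, at -1.25 and 0.29, and Cox6a2 and Ly6d, at -0.93 and -0.41.

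Genes of growth and proliferation were lower in 4-OHT. All 40 textbook MYC target genes were lower, 4 of them at least 2-fold, with a median of -0.58 (percentile 0). Npm1, a nucleolar protein gene, was at 1385 and 848 FPKM and Ldha, the lactate dehydrogenase gene, at 1064 and 723 FPKM, and the amino acid transporter gene Slc7a5 was lowest, at a log2 ratio of -1.44. All 48 compared ribosome biogenesis genes were lower (median -0.58), including Fbl, which encodes the nucleolar methyltransferase fibrillarin, at -0.66 and the polymerase subunit gene Polr1d at -0.73. The S phase list was lower in 40 of 40 members (median -0.66), with the replication clamp gene Pcna at -0.43 and Uhrf1 at -0.91. The list for G2 and mitosis was lower in 51 of 52 (median -0.69), with Top2a, a topoisomerase gene, at -1.18 and Cks1b at -0.57. The exception was Pttg1, the securin gene, at 6.70 and 15.0 FPKM. Of 28 genes of nucleotide and one-carbon synthesis, 26 were lower (median -0.72), and Shmt2, the serine hydroxymethyltransferase gene of mitochondria, was at 277 and 106 FPKM and Impdh2 at 146 and 102.5 FPKM. Each of these 5 lists lay at percentile 0. The nucleotide list shares 11 members and the MYC target list 10 with other lists. The pro-B and pre-B cell list, at -0.73, and the 7 lists of other cell types that stood apart, at 0.92 to 2.55, moved in the same comparison.

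Splicing genes were also lower, by less. In the list of core snRNP and spliceosome components, 59 of 66 members were lower, none of them by 2-fold, with a median of -0.35 (percentile 0.21). Its most abundant members were the Sm protein genes Snrpg (511 and 324 FPKM) and Snrpd2 (296 and 213 FPKM), 1.58-fold and 1.39-fold lower. Of 54 genes of SR and hnRNP splicing regulators, 49 were lower (median -0.41, percentile 0.06), with Hnrnpa2b1 at 502 and 381 FPKM and Hnrnpa3, in a row merged with a predicted gene, at 486 and 297 FPKM. In the list of the PRMT5 methylosome and the SMN complex, which loads Sm proteins onto snRNAs, 14 of 16 were lower (median -0.48, percentile 0.27). These values include Prmt5 itself. Besides Prmt5, the PRMT5 cofactor genes Wdr77 (28.3 and 18.9 FPKM) and Clns1a (85.3 and 64.3 FPKM) had log2 ratios of -0.56 and -0.40. Another cofactor gene, Coprs, listed as 2410022L05Rik, was higher, at 3.15 and 7.54 FPKM (log2 ratio 1.04). Smn1 (29.8 and 26.8 FPKM) was at -0.15 and Prmt1, the main asymmetric arginine methyltransferase gene, at -0.60. The oxidative phosphorylation list, an abundant housekeeping group, had a median of -0.28 (percentile 10.1), with Cox6a1 and Atp5b at -0.57 and -0.43. The translation factor list had a median of -0.39 (percentile 0.72), with Eef2 and Pabpc1 at -0.37 and -0.61. The monocyte and macrophage list, at 1.10, and the neutrophil list, at 2.55, moved the other way in this comparison. The median ratio of all genes fell with abundance, from 0.09 for means from 1 FPKM to -0.19 for means of 100 FPKM or more, which the matching of random lists allows for.

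**Figure D2:**
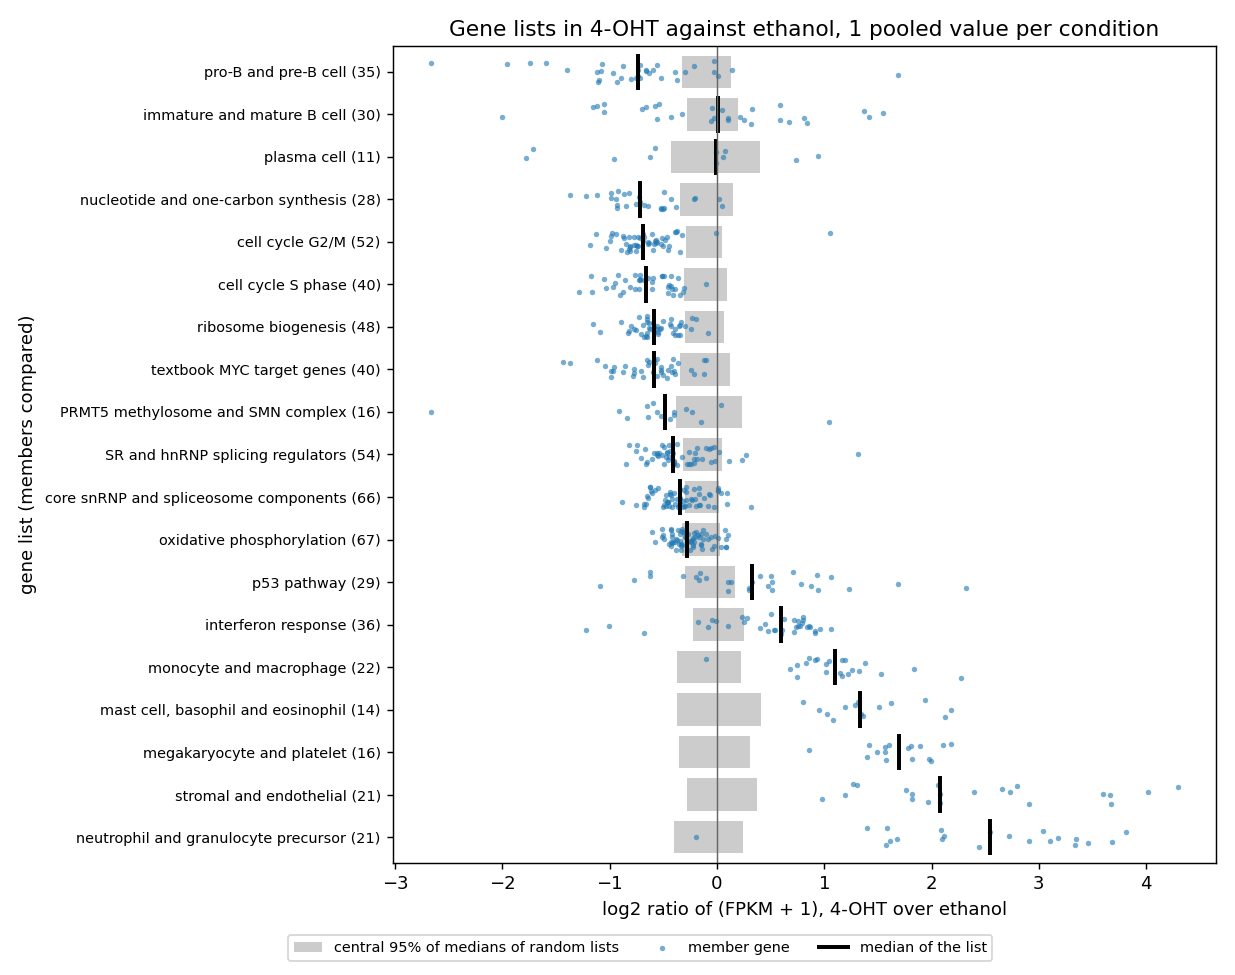
Log2 ratio of (FPKM + 1) in 4-OHT over ethanol (horizontal axis) for the members of 19 gene lists (vertical axis, number of compared members in brackets). Points are genes, black bars are list medians and grey bands hold the central 95% of medians of 10000 matched random lists; the medians ran from -0.73 for the pro-B and pre-B cell list to 2.55 for the neutrophil and granulocyte precursor list.

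Genes of the pathway of the tumour suppressor p53 were mostly higher in 4-OHT. In the p53 pathway list, 20 of 29 members were higher and 9 lower, with a median of 0.32 (percentile 99.8). The highest ratios were those of Phlda3, at 1.82 and 13.1 FPKM (log2 ratio 2.32), the cell cycle inhibitor gene Cdkn1a, at 21.3 and 70.5 FPKM (1.68), and the death receptor gene Fas, at 2.22 and 6.55 FPKM. The p53 target genes Rrm2b and Btg2 were lower, at -0.78 and -0.62. Trp53 itself was at 93.6 and 87.2 FPKM, and Cdkn2a, the locus of the p53 activator ARF, was 2.13-fold lower, at 189 and 88.2 FPKM. The BCL2 family list, which shares Bax, Bbc3 and Pmaip1 with the p53 list, had 12 of 16 members higher and a median of 0.34 (percentile 97.8), with Mcl1, an anti-apoptotic gene, at 116 and 157 FPKM and Bax, a pro-apoptotic gene, at 73.2 and 105 FPKM. Bcl2l1, an anti-apoptotic gene, was lower, at 82.3 and 46.5 FPKM. The BCL2 family list no longer stood apart with a pseudocount of 0.1 or with the authors' deposited fold changes. In the same comparison the monocyte and macrophage list was at 1.10 and the neutrophil list at 2.55.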

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

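The alternatives that use the authors' deposited fold changes, that leave out small RNAs and merged rows, or that leave out the members of the lists of other cell types were chosen after the data were seen. The count of genes at least 2-fold lower was 280, against 457 with a pseudocount of 0.1 and 482 with the authors' deposited fold changes, which have none. The count of genes at least 2-fold higher was 1124, against 700 with a minimum of 5 FPKM, where fewer genes were compared (8129). Under the other alternatives both counts stayed within 1.5 times, at 953 to 1334 higher and 198 to 384 lower. Without the members of the lists of other cell types, 1034 genes were higher and 279 lower. This removed listed members alone and left 10729 rows, with Col6a1, Mgp and Spp1 among them. It does not measure how many of the higher genes come from other cells. Of 42 named genes at least 2-fold different, all kept their direction under every alternative that shifted values, and 40 stayed past 2-fold under median-of-ratios scaling. The Prmt5 ratio ran from -2.86 to -2.57 and the Myc ratio from -0.97 to -0.81. Of the 22 lists called apart, 22 stayed so under quantile normalization. With a minimum of 5 FPKM, 19 of them could be compared and 19 stayed apart; those of natural killer cells, erythroid cells and histones had under 5 members left. Calls were lost for natural killer cells, the BCL2 family (pseudocount of 0.1, authors' deposited fold changes) and erythroid cells (no filter), and gained for dendritic cells and class II presentation. The histone median ran from 0.43 to 1.36, the stromal from 1.93 to 3.57 and the interferon from 0.34 to 0.76. The medians of the MYC/MAX, immature and mature B cell, plasma cell and interleukin 7 lists, all within the random lists, lay on both sides of 0. Median-of-ratios scaling moved the median ratio of all genes from -0.07 to 0.02. No paired analysis was possible because the table gives 1 pooled value per condition, and for the same reason limma with and without a trend, robust or array-weighted fits, the replicate block, leaving out each of the 6 libraries, camera with an estimated correlation, fry and other splits of the libraries were not run. Precision cannot be stated from FPKM without counts, and low values carry the least of it.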

Other observations

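The interferon response list had a median log2 ratio of 0.60 (percentile 99.99), with 29 of 36 members higher, 1 of them by at least 2-fold. Its most abundant members, Ly6e and Bst2, were at -0.05 and 0.76, and the guanylate-binding protein genes Gbp3 and Gbp2 were at -1.22 and -1.01. The immediate early and heat shock list had a median of 0.65 (percentile 100), with the transcription factor gene Fos at 31.1 FPKM in ethanol and 66.9 FPKM in 4-OHT, Zfp36 at 59.4 and 104 FPKM, and Hspa8 at 919.5 and 770.4 FPKM. In the same comparison the monocyte and macrophage list was at 1.10 and the neutrophil list at 2.55. The list of the integrated stress and unfolded protein responses had a median of -0.25 (percentile 16.8), and its members went apart. The serine and asparagine synthesis genes Phgdh (309 and 143 FPKM), Psat1 (206 and 102 FPKM) and Asns (158 and 68.4 FPKM) were lower, while the chaperone gene Calr was at 257 and 403 FPKM and Hsp90b1 at 294 and 290.3 FPKM.

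The next 4 lists lay within the random lists. The glycolysis list had a median of -0.15 (percentile 42.7), with Pkm2 at -0.24 and Ldha at -0.56, and the glucose transporter gene Slc2a3 at 1.30. The cholesterol synthesis list was at 0.16 (percentile 96.0), with Fdps at 0.72 and Srebf2 at -0.24. The list of Polycomb, DNA methylation and arginine methyltransferase genes was at -0.24 (percentile 10.9), with Ezh2 at -0.73 and Dnmt1 at -0.50. The MYC/MAX network list was at -0.16 (percentile 40.3) and at 0.02 with no filter on low values, with Mxd4 at -0.26 and Mxd1, a gene of a MYC antagonist, at 1.57. Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, stood above the random lists, with a median of 0.81 over 12 members (percentile 99.4), and 0.43 under quantile normalization. Its most abundant members, Hist1h2bc and Hist1h1c, were at 1.18 and 1.04, and most others had low values. The monocyte and neutrophil lists, at 1.10 and 2.55, moved in the same direction. Of the nuclear retained RNAs, too few to compare as a list (4), Neat1 was at 70.2 and 131 FPKM and Snhg1 at 114 and 58.6 FPKM. The Y-linked genes Eif2s3y (30.4 and 22.1 FPKM) and Ddx3y (13.3 and 14.4 FPKM) were detected in both conditions, and Xist was at 0.0197 FPKM in ethanol and 0.0131 FPKM in 4-OHT.

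The tests in the next paragraphs were chosen after the results were seen. The directions of the Prmt5 and Myc ratios under each reading of the labels were stated before. Those predictions asked for an adjusted p-value or a standard error, which could not be computed. Limits on the size of the ratios were used in their place and were set afterwards.

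The first pattern is the lower pro-B and pre-B cell list beside higher lists of other cell types, of which 10 of 21 neutrophil and 9 of 22 monocyte members had a mean of at least 100 FPKM. The labels say that B cells were isolated and name no sort. Scaling between the conditions would shift both alike, and the pro-B median minus the monocyte median was -1.83. A smaller share of B-lineage cells among otherwise unchanged cells would raise all other types by one factor, but the lower quartile of the neutrophil list lay 0.43 above the upper quartile of the monocyte list, so this alone does not account for the pattern. FPKM values are relative and cannot tell a gain of some cells from a loss of others. A changed mixture in which other cell types changed by unequal factors remains open, and so does a changed program within B-lineage cells. The latter could explain the unequal ratios within the pro-B list, whose interquartile range was 0.62, but other cells of the culture use some of its members and the table has no values per cell, so this cannot be told apart from a changed mixture. The same openness holds for the lower MYC target, ribosome biogenesis, nucleotide, cell cycle, splicing and translation factor lists. It also holds for the higher p53, BCL2 family, interferon, immediate early and histone lists.

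The second pattern is the Prmt5 value itself and the labels. Fewer B-lineage cells with unchanged Prmt5 per cell would not lower Prmt5 beyond genes that only those cells use. Prmt5 (-2.67) lay below the lower quartile of the pro-B and pre-B list by more than the interquartile range of that list (a difference of -1.59 against 0.62). The difference exceeded that range under every alternative run, at -1.77 to -1.58, although the number of the 35 members with a lower ratio than Prmt5 was 0 as deposited and 1 (Vpreb2) under quantile normalization. Prmt5 thus lay below most of the list, but Vpreb2 was nearly as low as deposited, at -2.67. Other cells use some of the members, so the quartile does not bound the effect of fewer B-lineage cells. The comparison therefore cannot exclude that explanation. The direction and size of the Prmt5 ratio are consistent with the characteristics that name its deletion in the libraries titled PT. The Myc ratio of -0.91 runs against a Myc transgene in the libraries titled PT alone, but with no error for the value this cannot be decided from the Myc value.

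The third pattern is a set of high ethanol values listed at 0 in 4-OHT: Lyz2 (3835 FPKM), Psap (1981 FPKM), Ctsd (1953 FPKM), Ctsb (556 FPKM) and Fdft1 (16.0 FPKM). A loss of macrophage transcripts in 4-OHT would lower other macrophage genes, but 1 of 22 compared monocyte and macrophage members was lower. Failed estimates listed as 0 are a candidate explanation: of 6 rows with at least 1 FPKM in ethanol and 0 in 4-OHT, 5 have a fold change of 0 in the authors' deposited table and not an infinite one, and Ctsb and Fdft1 share one locus. In the other direction, Snord71 and Mir3960 are listed at 0 in ethanol and at 3413 and 1688 FPKM in 4-OHT. Both list an infinite fold change, unlike the 5 rows above, and both are small RNAs, for which FPKM is unstable.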
